A study of Mus musculus with 2 samples.

How the data were processed

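Lung cells were profiled by droplet single-cell RNA sequencing (10x Genomics) in 2 libraries, 1 after a sham operation and 1 taken 6 hours after hepatic ischemia-reperfusion (HIR), with 1 library per group. Per the labels, lungs were minced and digested at 37 °C with collagenase, elastase and DNase, red cells were lysed, and live cells were loaded. The deposited matrices hold a count per gene and cell barcode, in UMIs (unique molecular identifiers). Per the labels, the authors used Cell Ranger 6.0, STAR and Seurat 4.0 with the mouse genome mm10. Per the file headers, the matrices were written by cellranger 5.0.0. All 32883 features carry Ensembl rat gene identifiers (prefix ENSRNOG), so gene symbols were read as rat symbols. Values were whole numbers, and no barcode had fewer than 500 UMIs.

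The sham library held 10719 barcodes and 59566745 UMIs, the HIR library 9499 barcodes and 50801778 UMIs, with a median of 3426 and 3094 UMIs and 1324 and 1218 genes per barcode. Barcodes with at least 200 genes and at most 20% mitochondrial UMIs were kept (9438 and 8593). Doublets were scored with Scrublet in scanpy 1.11.5, and the barcodes with the highest scores were left out at the rate of 0.8% per 1000 barcodes (919 and 722 called, 864 and 668 of them past the filter). This left 8574 sham and 7925 HIR cells.

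Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen within libraries (without mitochondrial, ribosomal, hemoglobin, sex-linked, immune receptor and immediate early genes), and 30 principal components were computed for both libraries together. Cells were clustered by the Leiden method (igraph 0.11.9) on a graph of 15 neighbours at resolution 1.0. Clusters were named from marker lists. A name needed at least 3 markers over 2-fold above the other clusters and a score of at least 0.8. The score was the mean log2 fold of the markers over the other clusters. Candidate names were ranked by the score plus 0.5 for each marker among the 10 leading genes of a cluster. The score, its threshold and this ranking were set after the data were seen. Clusters with 100 CPM of Ptprc counted as immune. Clusters with the same name were joined, as were unnamed clusters that shared at least 4 of their 10 leading genes. Names carry the suffix -like, and clusters that missed a requirement stayed unnamed. For 32 listed symbols that the feature table gives under a rat symbol, the rat symbol was used; these were chosen after the feature table was seen. Gene lists, marker lists, ligand and receptor pairs, the alternatives below and the rule for named genes were chosen before the data were examined.

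The share of each class among all kept cells was given with an exact binomial interval, and the ratio of shares with a 95% interval. Within each of the 17 classes with at least 100 cells in both libraries, UMIs were summed per gene and divided by the class total, as CPM (counts per 1000000 UMIs). Fold values are ratios of these CPM with exact 95% counting intervals. Log2 ratios were taken after 10 CPM was added to both values. A gene was eligible to be named with at least 100 CPM in either library and at least 50 UMIs over both. The interval of its ratio had to leave out 1. To set aside free RNA, it also needed at least 5% of the level of the class with the most of it. The estimated free RNA share was above 5% in HIR alveolar type 1-like (12.9%) and neutrophil-like cells (9.80%), where free RNA alone could pass. Markers of other classes and mitochondrial, ribosomal, hemoglobin, sex-linked and immune receptor genes were left out. The 10 genes with the largest difference in each direction were named in the 6 largest classes, and 3 in the other classes, apart from a few that were not used here; genes over 2-fold apart in at least 75% of 5 or more classes were named as shared. Other genes in the text are members of the pairs, or of the gene lists with a high level or a large ratio, and Tf in neutrophil-like cells was named after its value was seen. A gene list was summarized by the median log2 ratio of its members with at least 20 CPM in either library, where at least 5 were measured. Its interval came from 500 Poisson draws of the counts. Its percentile is the position of the median among 10000 random lists matched by size and level. A pair was reported where its ligand or receptor was over 2-fold apart in a class with at least 50 CPM.

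With 1 library per group there was no test, and no count of genes was made from cells. The intervals hold the counting error alone. Tested on simulated data with genes changed by known factors, the intervals held the true ratio for 95.1% of genes in the general capillary endothelium-like class and 95.5% in the interstitial macrophage-like class. They excluded a ratio of 1 for 100.0% of the genes set 2-fold apart in both classes, for 100.0% and 91.0% of those set 1.5-fold apart and for 4.8% and 4.5% of the unchanged genes. The simulated counts held only the counting error that the intervals assume. The simulation thus checks the calculation and leaves out the spread between cells and between animals.

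The share of free RNA per class was estimated from genes the class lacks. These were S100a8 and S100a9 in epithelial classes and Sftpc and Scgb1a1 in all others. Where the estimate exceeded the level of a gene, all of that level was removed. For shares of cells with a UMI, each cell was also thinned to 1000 UMIs, which left out 427 sham and 403 HIR cells below that depth. The alternatives tried were no filter, a stricter filter (500 genes, 10% mitochondrial UMIs), doublets kept, Leiden resolution 2.0, each library clustered alone, each cell assigned alone by its markers, scaling to the median gene of the class, the mean of per-cell CPM, subtraction of free RNA, a pseudocount of 1 CPM, and all list members with a UMI. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9 were used. No reads were realigned, since counts alone were compared.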

Results

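Gene expression was measured in single lung cells by droplet sequencing (10x Genomics) in 2 libraries, 1 from a sham operation and 1 taken 6 hours after hepatic ischemia-reperfusion (HIR), in which the blood supply of the liver is blocked and then restored. The series asks how the immune cells of the lung, and their interactions, differ after HIR. The sham library held 59566745 UMIs (unique molecular identifiers, each standing for 1 captured transcript) over 10719 cell barcodes, with a median of 3426 UMIs per barcode, and the HIR library 50801778 UMIs over 9499 barcodes, with a median of 3094. After filtering, 8574 sham cells and 7925 HIR cells remained and fell into 23 classes, each called X-like from its markers or left unnamed. Gene symbols and identifiers are those of the files, whose 32883 features all carry rat Ensembl identifiers, while the labels name the mouse. The files give no genome coordinates. With 1 library per group there were no replicates and no test, so each value describes these libraries. Fold values are ratios of CPM (counts per 1000000 UMIs of the class), and log2 ratios were taken after 10 CPM was added to both values. Intervals in parentheses are 95% intervals that cover counting error only.

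The clearest difference in cell makeup was among myeloid cells. Neutrophil-like cells, phagocytes that blood delivers to inflamed tissue, made up 4.41% (3.98 to 4.86, 378 cells) of the sham library and 16.2% (15.4 to 17.0, 1280 cells) of the HIR library, a ratio of 3.66 (3.26 to 4.12). Classical monocyte-like cells, the inflammatory blood monocytes, made up 1.95% (1.67 to 2.26, 167 cells) of the sham library and 4.34% (3.9 to 4.81, 344 cells) of the HIR library, a ratio of 2.23 (1.85 to 2.70). Nonclassical monocyte-like cells, which patrol the vessel wall, went the other way, with 4.72% and 2.86% and a ratio of 0.606 (0.513 to 0.715). This class was not named in both libraries without a filter, with a stricter filter, at Leiden resolution 2.0 or with each library clustered alone. Its ratio has no value there. All immune classes together held 36.1% of the sham cells and 44.0% of the HIR cells, and counted among immune cells alone the ratios were 3.001 for neutrophil-like, 1.83 for classical monocyte-like and 0.497 for nonclassical monocyte-like cells. The neutrophil-like ratio was 5.58 with a stricter filter and 5.71 with each cell assigned alone. Sham neutrophil-like cells had a median of 1366 UMIs and HIR ones 2086. The files held no barcode under 500 UMIs.

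B cell-, T cell- and fibroblast-like cells held smaller shares of the HIR library. B cell-like cells were at 9.48% and 6.71% (ratio 0.708 (0.633 to 0.791)), T cell-like cells at 3.55% and 2.78% (ratio 0.783 (0.655 to 0.934), or 0.979 with each library clustered alone and 0.892 without a filter), and NK cell-like cells at 1.89% and 2.01% (ratio 1.06 (0.848 to 1.33)). Alveolar fibroblast-like cells, the matrix-making cells of the alveolar wall, made up 4.25% and 1.69% (ratio 0.398 (0.324 to 0.487), or 0.724 with each cell assigned alone), and adventitial fibroblast-like cells 4.07% and 2.91% (ratio 0.716 (0.604 to 0.848)). Ratios were also taken among non-immune cells alone. They were 0.455 for alveolar and 0.818 for adventitial fibroblast-like cells, 0.992 for clusters 3 and 5 and 1.09 for smooth muscle or myofibroblast-like cells. Venous endothelium-like cells were at 1.84% and 2.69% (ratio 1.46 (1.18 to 1.80)), while general capillary, aerocyte capillary and alveolar type 2 epithelium-like cells and smooth muscle or myofibroblast-like cells had ratios of 0.924 (0.854 to 1.0), 0.98 (0.866 to 1.11), 0.939 (0.79 to 1.12) and 0.954 (0.843 to 1.08). The general capillary ratio was 1.12 at Leiden resolution 2.0, the aerocyte ratio 0.638 with each library clustered alone and 1.13 without a filter, and the smooth muscle or myofibroblast ratio 0.578 with a stricter filter. The alveolar type 1 epithelium-like ratio of 1.45 (1.17 to 1.80) included cluster 30, 40 cells that came from the HIR library alone and may be that library rather than a cell type. Cluster 30 had a median of 972 UMIs, and its second-best name was general capillary endothelium (score 0.947 against 1.05). The rest of the class, cluster 1, held 156 sham and 169 HIR cells. Erythroid-like cells made up 2.71% and 1.07% (ratio 0.396 (0.305 to 0.51), or 0.812 with a stricter filter). The protocol lysed red cells. Their median UMIs were 7096 and 1275. Among the other classes, basophil or mast cell-like cells had a ratio of 0.734 (0.56 to 0.959), lymphatic endothelium-like cells 0.56 (0.345 to 0.892), conventional type 2 and plasmacytoid dendritic cell-like cells 0.984 (0.717 to 1.35) and 0.905 (0.611 to 1.33), club cell-like cells 0.872 (0.515 to 1.46) and interstitial macrophage-like cells 0.871 (0.679 to 1.12).

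The unnamed clusters 3 and 5, led by Lum, Dcn, Wnt11 and other stromal genes, held 16.0% and 13.9% of the libraries. Their marker scores lay under the naming threshold, which was set after the data were seen. Cluster 11, immune cells led by Plet1, Fabp4 and Krt79, held 4.96% and 4.81% and had fewer than the 3 markers a name required. The ratio of clusters 3 and 5 was 0.869 (0.802 to 0.941), but 1.07 without a filter, 1.21 with a stricter filter and 1.16 with each library clustered alone.

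**Figure D1:**
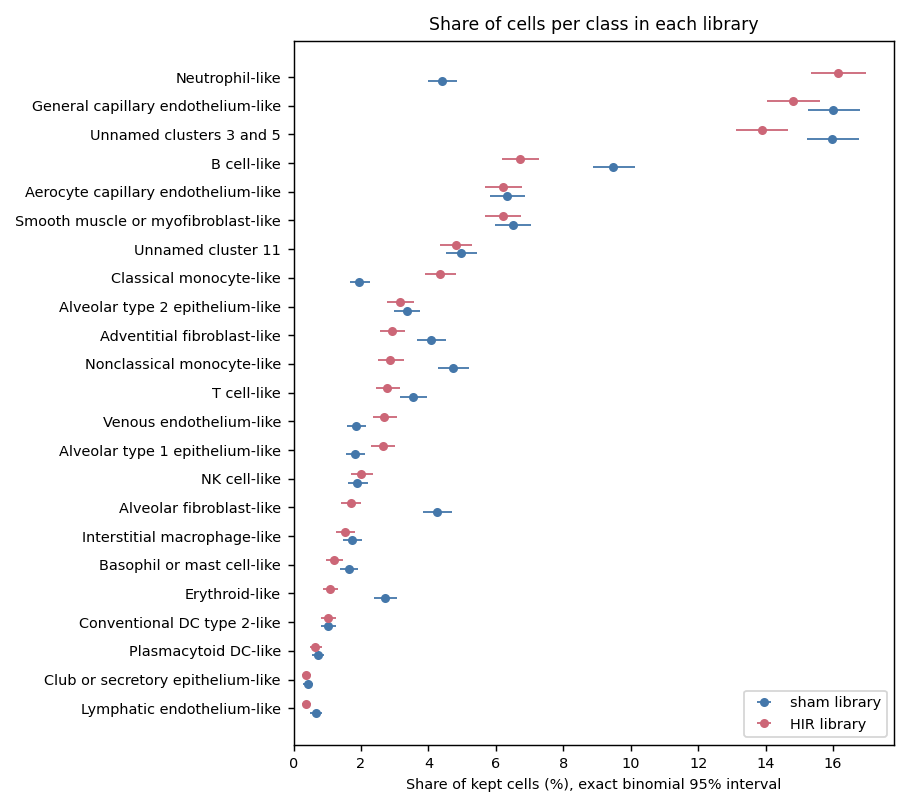
Share of all kept cells (percent, horizontal axis) in each cell class for the sham library and the HIR library, 1 library each, with exact binomial 95% intervals that cover counting error only. Neutrophil-like cells stood at 4.41% and 16.2% and classical monocyte-like cells at 1.95% and 4.34%, while nonclassical monocyte-like, alveolar fibroblast-like and erythroid-like cells held smaller shares of the HIR library.

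The glucocorticoid response was higher in the HIR library in each of the 9 compared non-immune classes. It is a list of genes that the receptor for corticosterone and cortisol induces. In adventitial fibroblast-like cells 18 of 18 measured members were higher in the HIR library, 12 of them over 2-fold, with a median log2 ratio of 1.35 (1.16 to 1.46). The counts were 16 of 16 in alveolar fibroblast-like cells (median 1.30 (1.08 to 1.41)), 17 of 17 in clusters 3 and 5 (1.08 (0.95 to 1.19)), 16 of 16 in smooth muscle or myofibroblast-like cells (0.97 (0.78 to 1.12)), 12 of 13 in general capillary (0.96 (0.68 to 1.05)), 13 of 13 in aerocyte (0.89 (0.76 to 1.14)) and 13 of 15 in venous endothelium-like cells (0.91 (0.85 to 1.02)). In alveolar epithelium the medians were 1.13 (0.92 to 1.43) for type 1-like and 0.69 (0.51 to 0.77) for type 2-like cells. In type 2-like cells the members Mt1 and Mt2A were lower (log2 ratios -1.52 and -1.28). Each of these 9 medians lay at the 100.0 percentile of 10000 random lists of like size and level, which describes these libraries only. Of the immune classes, interstitial macrophage-like cells had a median of 0.74, above that of type 2-like cells. The medians were 0.45 in NK cell-like, 0.12 in B cell-like and 0.04 in T cell-like cells.

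The members at the front differed by class. Cebpd (ENSRNOG00000050869), a transcription factor of the acute response, was higher in the HIR library by 3.66-fold (3.45 to 3.89) in general capillary endothelium-like cells, 5.23-fold in venous endothelium-like and 3.96-fold in alveolar fibroblast-like cells. Ddit4 (ENSRNOG00000057078), an inhibitor of the growth kinase complex mTORC1, was 2.98-fold (2.78 to 3.20) higher in general capillary endothelium-like cells (272 and 811 CPM in the sham and HIR libraries) and 6.63-fold (4.50 to 10.1) higher in alveolar type 1-like cells. Tsc22d3 (ENSRNOG00000056135), which codes for the anti-inflammatory protein GILZ, stood at 1151 and 3135 CPM in adventitial fibroblast-like cells and 735 and 1639 CPM in smooth muscle or myofibroblast-like cells, but at 489 and 417 CPM in general capillary endothelium-like cells. Fkbp5 (ENSRNOG00000022523), a co-chaperone of the glucocorticoid receptor, was 3.75-fold (2.63 to 5.41) higher in adventitial and 3.75-fold (2.07 to 6.88) in alveolar fibroblast-like cells. Angptl4 (ENSRNOG00000007545), an inhibitor of lipoprotein lipase, was 9.31-fold (6.196 to 14.5) higher in adventitial fibroblast-like cells and 11.4-fold (8.46 to 15.6) in clusters 3 and 5. Many of these genes also answer to other signals: Ddit4 and Angptl4 to hypoxia and fasting, Cebpd to inflammation.

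Different clusters held most general capillary endothelium-like cells of each library (cluster 2 held 96.3% in sham, cluster 28 held 78.6% in HIR). Within cluster 2 the median of the glucocorticoid list was 0.51 and within cluster 28 0.66. Including members under 20 CPM, it was 0.45.

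**Figure D2:**
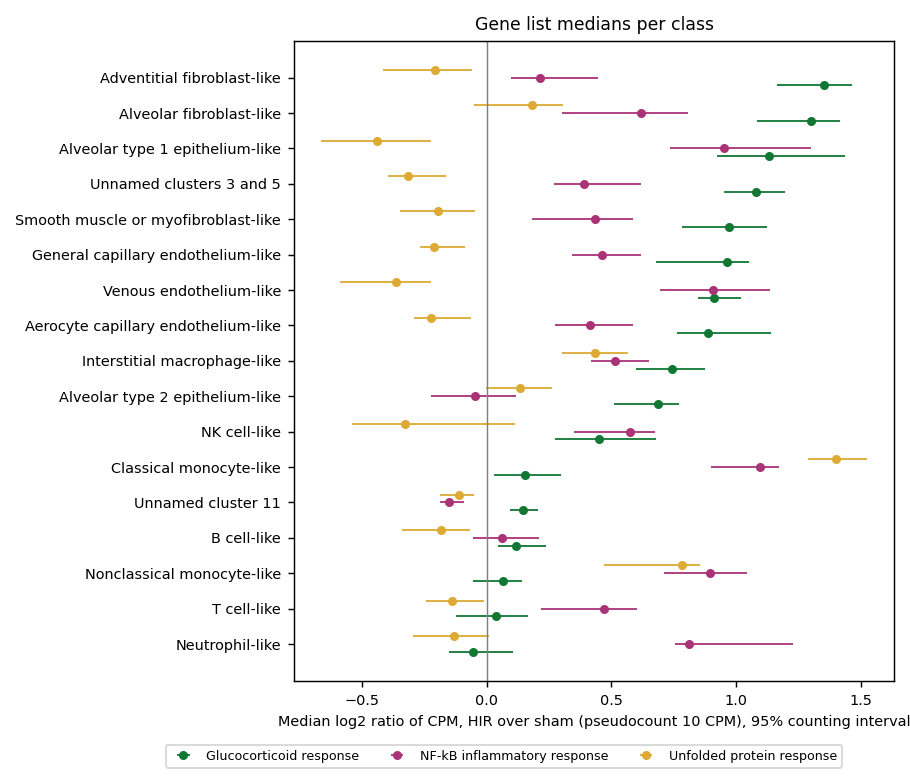
Median log2 ratio of CPM, HIR over sham (horizontal axis), of the glucocorticoid, NF-kB and unfolded protein response lists in the compared cell classes, 1 library per group, with 95% counting intervals as lines. The glucocorticoid list stood at 0.69 or higher in all 9 compared non-immune classes, and the unfolded protein response was highest in classical monocyte-like cells (1.40).

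**Figure D3:**
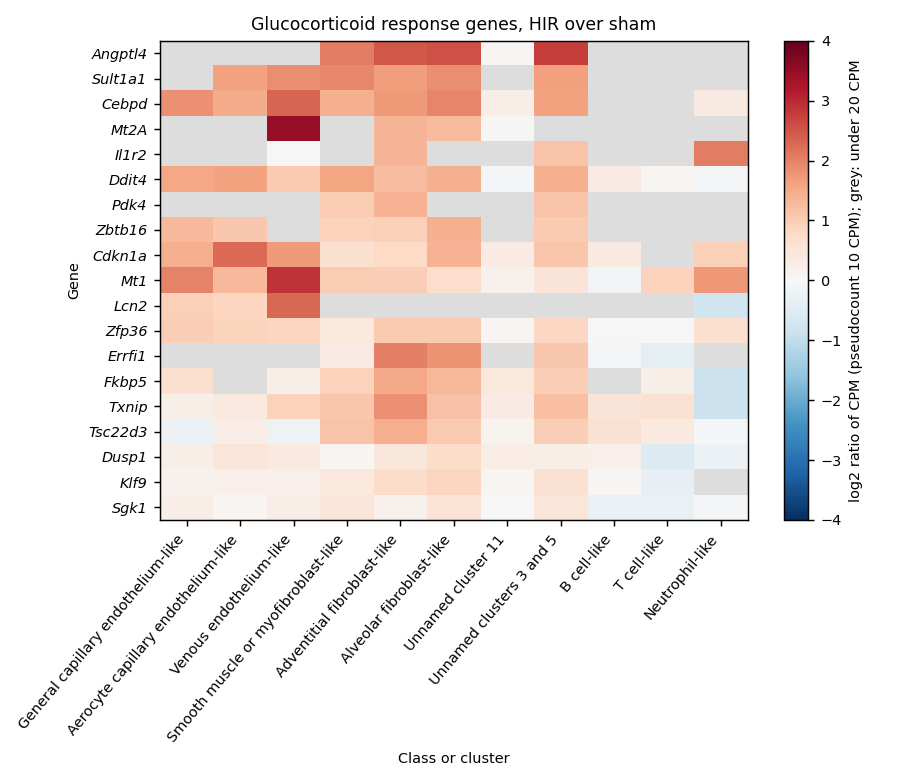
Log2 ratio of CPM, HIR over sham (color scale), of glucocorticoid response genes (vertical axis) in the cell classes (horizontal axis), 1 library per group, with gray for genes under 20 CPM in both libraries. Angptl4 was among the highest in fibroblasts (2.49 in adventitial fibroblast-like cells) and Mt2A in venous endothelium-like cells (3.49), while B cell-like and T cell-like cells stood near 0.

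Among capillary endothelium-like cells, Gpx2, Xdh and Slc43a3 were higher and Wfdc1 was lower in the HIR library. Gpx2 (ENSRNOG00000055672), a glutathione peroxidase, was 50.6-fold (34.6 to 77.2) higher in general capillary endothelium-like cells (6.24 and 316 CPM) and 15.3-fold (10.96 to 22.1) higher in aerocyte-like cells, the large capillary cells of gas exchange. Xdh (ENSRNOG00000007081), the enzyme that makes uric acid and can release superoxide, was 5.37-fold (4.52 to 6.41) and 3.06-fold (2.64 to 3.54) higher, and Slc43a3 (ENSRNOG00000061768), a purine nucleobase transporter, 4.43-fold (4.02 to 4.89) and 3.30-fold (2.94 to 3.70) higher. Nfkbia (ENSRNOG00000007390), the inhibitor that NF-kB itself induces, was 4.00-fold (3.81 to 4.21) and 3.48-fold (3.26 to 3.72) higher. Wfdc1 (ENSRNOG00000015904), a secreted protein of the whey acidic family that is also a leading gene of cluster 2, was lower in both, at 2549 and 499 CPM in general capillary and 970.4 and 200.3 CPM in aerocyte-like cells. Of the list of NRF2 and oxidative stress, 7 of 12 measured members were higher in general capillary (median log2 ratio 0.16 (-0.04 to 0.25)) and 6 of 11 in aerocyte-like cells (0.02 (-0.12 to 0.23)), none over 2-fold. The surfactant and type 2 list, which also holds genes of other cells such as Lyz2, was higher in the same cells. Of its members, 8 of 9 were higher in general capillary (median 0.62 (0.42 to 0.79)) and 10 of 11 in aerocyte-like cells (0.81 (0.57 to 0.98)). Sftpc itself stood at 493 and 619 CPM in general capillary and 487 and 676 CPM in aerocyte-like cells. In aerocyte-like cells the log2 ratio of Ager, a gene of type 1 epithelium, was 1.94, or 0.48 with doublets kept. Type 1-like cells themselves held Gpx2 at 995 and 891 CPM and Ager at 20540 and 15190 CPM, while Ager stood at 42.5 and 68.8 CPM in general capillary endothelium-like cells.

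Further genes higher in general capillary endothelium-like cells were Arl4a, the growth factor signalling inhibitor Spry1, the basement membrane collagen Col4a3 and the interleukin 6 family receptor Il6st (2.98- to 3.69-fold). Lower were the lactate dehydrogenase subunit Ldhb (4.85-fold (3.81 to 6.25) lower), the serotonin transporter Slc6a4 (3.02-fold (2.46 to 3.72)), the Notch target Nrarp (2.68-fold (2.21 to 3.27)), the cell cycle gene Ccnd1 (2.35-fold (2.15 to 2.57)) and Emp1, Cald1, Anxa3, Crip1 and Azin1 (2.39- to 3.52-fold). The aerocyte-like class joined clusters 10 and 18. Cluster 18 had general capillary endothelium as its second-best name, with the higher marker score (2.01 against 1.31). It held 41.4% of the sham and 35.8% of the HIR cells of the class, and aerocyte-like levels were not split by cluster. In aerocyte-like cells, Apln, the peptide hormone that marks this cell, was 2.95-fold (2.68 to 3.24) lower and the endothelial transcription factor Sox18 2.30-fold (2.06 to 2.58) lower, beside Ldhb, Crip1, Nsg1 and the matrix genes Col15a1, Hmcn1, Htra1 and Olfml2a (2.44- to 4.22-fold), and Arl4a was 2.73-fold (2.37 to 3.15) higher. Anxa8, Sec14l4 and Gsta4 were 3.83- to 6.54-fold higher in aerocyte-like cells, but with doublets kept their log2 ratios were 0.79, 0.62 and 0.81. Averaged per cell, the log2 ratio of Gpx2 in aerocyte-like cells was 2.28 instead of 3.19. Of the genes of endothelial junctions and barrier, 7 of 17 measured members were higher in general capillary and 4 of 17 in aerocyte-like cells, none over 2-fold either way. Cdh5, the adhesion molecule of endothelial junctions, stood at 1643 and 1135 CPM in general capillary endothelium-like cells.

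Venous endothelium-like cells carried the leukocyte adhesion genes. Selp (ENSRNOG00000002794) and Sele (ENSRNOG00000002723), the selectins on which leukocytes roll, were 7.60-fold (4.60 to 13.4) and 6.35-fold (3.38 to 13.2) higher in the HIR library, from 17 and 159 UMIs and 11 and 86 UMIs. Vcam1 (ENSRNOG00000014333), the ligand of monocyte and lymphocyte integrins, was 2.13-fold (1.94 to 2.35) higher and Icam1 (ENSRNOG00000020679) 1.64-fold (1.46 to 1.85) higher. The metallothioneins Mt2A (ENSRNOG00000043098) and Mt1 (ENSRNOG00000038047), metal-binding proteins, were 12.2-fold (10.3 to 14.6) and 7.91-fold (6.77 to 9.28) higher, and the iron carrier Tf (ENSRNOG00000030625) 13.3-fold (10.9 to 16.3) higher. Tf was also abundant in neutrophil-like cells (4457 and 3007 CPM), and S100a8, a neutrophil gene, stood at 11.6 and 858 CPM in venous endothelium-like cells.

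Of the NF-kB list, 13 of 13 measured members were higher in venous endothelium-like cells (median log2 ratio 0.91 (0.69 to 1.13), or 0.60 with members under 20 CPM), among them Nfkbia (2.94-fold (2.75 to 3.15)) and the monocyte growth factor Csf1 (2.71-fold (1.82 to 4.13)). Of the list of endothelial activation 5 of 10 were higher, with Thbd, the anticoagulant thrombomodulin, at 2678 and 1605 CPM. Duoxa1, a maturation factor of the oxidase DUOX1, was 38.2-fold (16.0 to 119) lower, Wfdc1 8.57-fold (7.27 to 10.2) lower and Amigo2 5.48-fold (4.48 to 6.75) lower. Of the unfolded protein response, 12 of 13 members were lower (median -0.36 (-0.59 to -0.22)), with Calr at 785 and 364 CPM. With doublets kept, the log2 ratio of Selp was 1.58.

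In the unnamed stromal clusters 3 and 5, genes of the matrix list were mostly lower in the HIR library, but not within cluster 3. Among named genes, Igfbp3 (ENSRNOG00000061910), a binding protein of insulin-like growth factors, was 11.7-fold (9.14 to 15.2) higher, Pfkfb3 (ENSRNOG00000018911), a regulator of glycolysis, 8.11-fold (6.11 to 10.95) higher and the Wnt antagonist Sfrp1 (ENSRNOG00000017783) 4.39-fold (3.68 to 5.25) higher. Lower in the same clusters were Loxl1 (ENSRNOG00000008680), a cross-linking enzyme of elastic fibers (3.40-fold (2.86 to 4.06)), Ccn2 (ENSRNOG00000015036), a matricellular protein (2.95-fold (2.67 to 3.25)), Serpinh1 (ENSRNOG00000016831), the chaperone of collagen folding (2.93-fold (2.67 to 3.23)), and Igfbp5 (5.52-fold (4.63 to 6.62)). Of the fibroblast matrix list, 13 of 16 measured members were lower (median log2 ratio -0.63 (-0.66 to -0.58)), with Col3a1 at 10880 and 5112 CPM and Acta2, the actin of contractile cells, at 563 and 205 CPM. The libraries lay mostly in different clusters here (cluster 3 held 84.7% of the sham cells, cluster 5 90.1% of the HIR cells), and within cluster 3 the matrix median was 0.02, within cluster 5 -0.18. With a stricter filter the log2 ratio of Acta2 was -0.50, and with free RNA subtracted that of Crip1 was -3.25 instead of -2.54.

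Other genes of clusters 3 and 5 were Crispld2, Cebpd, Sesn1, Sash1, Nfkbia and Xdh, 2.75- to 4.18-fold higher, and the retinoic acid-binding protein Crabp1 with Crip1, Kazald1, C1qtnf2 and Spink8, 3.36- to 6.91-fold lower. In smooth muscle or myofibroblast-like cells, Sult1a1 (ENSRNOG00000019342), a sulfotransferase, was 4.18-fold (3.55 to 4.94) higher, and Pink1, a kinase of mitochondrial quality control, 2.84-fold (2.35 to 3.45) higher, beside Sncg, Nfkbia, Ddit4, Cebpd, Xdh and Sesn1 (2.70- to 4.10-fold). The class joined clusters 15 and 7. The second-best name of cluster 7 was pericyte. It held 38.1% of the sham and 27.7% of the HIR cells of the class. The lower levels of Heyl, Postn, Vtn and Pcdh18 were not split by cluster. The Notch target Heyl was 3.27-fold (2.496 to 4.34) lower, Serpinh1 2.26-fold (2.03 to 2.52) lower and Pcolce, an enhancer of procollagen processing, 2.14-fold (1.80 to 2.56) lower, beside Wfdc1, Septin4 and Pmepa1 (2.31- to 2.49-fold). Of the matrix list 13 of 16 measured members were lower in these cells (median -0.42 (-0.50 to -0.36)), with Eln at 3829 and 2449 CPM and Postn at 553 and 123 CPM. Gpx3, a leading gene of cluster 5, was 3.39-fold (3.12 to 3.69) higher and Vtn, Pcdh18 and Pde5a 2.29- to 4.03-fold lower in smooth muscle or myofibroblast-like cells, but with a stricter filter their log2 ratios were 0.86, -0.99, -0.54 and -0.40.

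In adventitial fibroblast-like cells the genes Ccl19, Ccl7 and Il33 were lower in the HIR library. Ccl19 (ENSRNOG00000015668), which guides T cells and dendritic cells, was 22.9-fold (11.9 to 50.5) lower, Ccl7 (ENSRNOG00000000239), a monocyte chemokine, 5.37-fold (4.26 to 6.85) lower and Il33 (ENSRNOG00000016456), an alarmin of barrier tissue, 3.99-fold (3.20 to 5.03) lower. Penk (ENSRNOG00000008943), the precursor of enkephalin peptides, was 7.84-fold (6.64 to 9.29) higher and Xdh 6.71-fold (5.54 to 8.18) higher. In alveolar fibroblast-like cells Xdh was 8.38-fold (6.77 to 10.5) higher, the Wnt antagonist Frzb 9.97-fold (6.38 to 16.1) higher and Angptl4 10.2-fold (6.07 to 18.1) higher, while Loxl1, C1qtnf2 and Hivep3 were 4.69- to 5.26-fold lower. Lox (ENSRNOG00000014426), another cross-linking enzyme of this family, stood at 284 and 1195 CPM in alveolar fibroblast-like cells. The matrix list as a whole had 7 of 15 members higher in adventitial and 6 of 15 in alveolar fibroblast-like cells (medians -0.00 and -0.16). With doublets kept, the log2 ratio of Ccl19 was -0.64.

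In summed counts, neutrophil-like cells of the HIR library had less RNA of granule formation and more of inflammatory signalling. Ngp (ENSRNOG00000024330), a granule protein of maturing neutrophils, was 31.7-fold (29.3 to 34.4) lower (6948 and 219 CPM), Camp (ENSRNOG00000020733), the antimicrobial cathelicidin, 4.88-fold (4.71 to 5.05) lower and Cebpe (ENSRNOG00000014282), the transcription factor of secondary granule genes, 13.4-fold (9.29 to 19.8) lower. Serpinb1a (ENSRNOG00000016581), an inhibitor of neutrophil elastase, was 13.8-fold (12.4 to 15.5) higher (434 and 5988 CPM), Tgm1 15.6-fold (7.10 to 42.7) higher and Alpl, the alkaline phosphatase of neutrophil secretory vesicles, 9.20-fold (5.09 to 18.6) higher. Il1r2 (ENSRNOG00000014378), the decoy receptor of interleukin 1, was 4.17-fold (3.73 to 4.68) higher, and Sod2 (ENSRNOG00000019048), the mitochondrial superoxide dismutase, 4.36-fold (4.09 to 4.66) higher. Il1b (ENSRNOG00000004649) itself stood at 6158 and 6228 CPM.

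Of the list of neutrophil immaturity and secondary granules, 8 of 11 measured members were lower, 5 over 2-fold, with a median log2 ratio of -0.78 (-0.89 to -0.71); Olfm4 (3.99-fold (3.50 to 4.56)) and the leukotriene B4 receptor Ltb4r (3.35-fold (2.499 to 4.59)) were higher. Across all genes of this class the median log2 ratio was -0.26, against which the list medians are to be set. Of the NF-kB list 16 of 19 members were higher (median 0.81 (0.75 to 1.23)), among them Nfkbia (5.38-fold (4.82 to 6.03)), Nfkbiz (3.31-fold (2.43 to 4.60)) and the apoptosis inhibitor Birc3 (7.01-fold (3.76 to 14.8)). The monocyte chemokine Ccl2 was 9.68-fold (8.51 to 11.01) lower. Of the list of neutrophil maturity and activation 14 of 20 members were higher (median 0.32 (0.22 to 0.48)), among them the protease inhibitor Slpi (2.52-fold (2.39 to 2.67)) and the prostaglandin synthase Ptgs2 (3.94-fold (2.51 to 6.53)), while Cxcr4, the receptor that holds neutrophils in the bone marrow, was 2.64-fold (2.26 to 3.07) lower and the chemokine Ccl6 2.95-fold (2.78 to 3.13) lower. The granulocyte receptors Csf3r and Cxcr2 stood at 381 and 554 CPM and 57 and 81.8 CPM. Of the list of classical macrophage activation 7 of 7 members were higher (median 1.51, or 0.14 with members under 20 CPM), with Nos2, the inducible nitric oxide synthase, at 8.14 and 86.7 CPM and the interferon-induced chemokine Cxcl10 at 2.71 and 85.2 CPM.

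The neutrophil-like cells of the libraries lay in different clusters: cluster 4 held 83.1% of the sham cells and cluster 22 held 97.9% of the HIR cells. Ngp, Camp, Olfm4, Mmp8, Serpinb1a and Il1r2 were among the 10 leading genes of cluster 22, and Il1b and Osm among those of cluster 4. Within cluster 4 (314 sham and 27 HIR cells) the median of the immaturity list was -1.96 and that of the NF-kB list 0.32. Within cluster 22 (64 sham and 1253 HIR cells) they were -1.56 and 2.22. The classical macrophage activation median was 0.30 and 2.51 in these clusters. Averaged per cell, so that each cell weighed the same, the median of the immaturity list was -0.09 and the log2 ratios of Il1b, Serpinb1a, Ngp, Camp and Cebpe were -0.18, 4.37, -4.12, -1.14 and -2.04, against 0.02, 3.76, -4.92, -2.28 and -2.97 from summed counts. With a stricter filter that of Cxcl10 was 2.30 instead of 2.90.

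Classical monocyte-like cells of the HIR library had more RNA of the unfolded protein response and NF-kB lists, while some cytokine genes were higher and others lower. Cxcl1 (ENSRNOG00000002802) and Cxcl2 (ENSRNOG00000002792), chemokines that draw neutrophils through CXCR2, were 7.28-fold (6.09 to 8.78) and 2.76-fold (2.60 to 2.94) higher. Il6 (ENSRNOG00000010278) was 18.6-fold (8.93 to 46.6) higher from 7 and 375 UMIs, Cxcl10 (ENSRNOG00000022256) 16.1-fold (8.06 to 37.4) higher, and Il1b stood at 1592 and 3414 CPM. Hspa5 (ENSRNOG00000018294), the chaperone BiP of the endoplasmic reticulum, was 2.99-fold (2.79 to 3.21) higher, and its companions Creld2 (ENSRNOG00000004659) and Hyou1 (ENSRNOG00000010944) 9.94-fold (5.85 to 18.3) and 5.24-fold (3.60 to 7.92) higher. The monocyte chemokines Ccl2 and Ccl7 were 3.72-fold (3.55 to 3.89) and 17.7-fold (11.1 to 29.6) lower.

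Of the unfolded protein response list, 13 of 13 measured members were higher in classical monocyte-like cells, 8 over 2-fold (median 1.40 (1.29 to 1.52)), 10 of 12 in nonclassical monocyte-like cells (0.78 (0.47 to 0.86)) and 11 of 12 in interstitial macrophage-like cells (0.43 (0.30 to 0.57)); the stress transcription factors Atf4 and Ddit3 stood at 611 and 625 CPM and 234 and 259 CPM in the classical class. Of the NF-kB list 20 of 23 members were higher in classical (median 1.10 (0.90 to 1.17)) and 20 of 21 in nonclassical monocyte-like cells (0.90 (0.71 to 1.04)). Further genes lower in the classical class were Ramp1, the receptor partner of calcitonin gene-related peptide (10.8-fold (8.29 to 14.3)), Popdc2 and Epsti1 (9.65-fold and 10.4-fold), and Arl5c was 7.67-fold (6.09 to 9.78) higher. In nonclassical monocyte-like cells, Rgs1, a brake on chemokine receptor signalling, was 27.9-fold (14.8 to 59.3) higher, Retn 16.6-fold (10.5 to 27.7) higher and Arl5c 10.4-fold (8.62 to 12.6) higher, while the potassium channel gene Kcnn4, Hmgn3 and Pdcd4 were 5.42- to 10.1-fold lower. Cd14 (ENSRNOG00000017819), the co-receptor for bacterial lipopolysaccharide, was 9.17-fold (7.36 to 11.5) higher and Acod1, which makes itaconate, 25.01-fold (9.30 to 94.6) higher there. Of the list of neutrophil maturity and activation, 18 of 19 members were higher in nonclassical monocyte-like cells (median 1.12 (0.99 to 1.27)). These cells also held more of the neutrophil gene S100a8, at 16.1 and 316 CPM. S100a8 in classical monocyte-like cells stood at 1158 and 16750 CPM.

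In interstitial macrophage-like cells Cxcl10 (ENSRNOG00000022256) was 3.63-fold (2.76 to 4.81) higher, the chemokine Ccl4 (ENSRNOG00000011406) 2.94-fold (2.52 to 3.44) higher and the lipid hydrolase Pla2g7 5.76-fold (3.64 to 9.48) higher, while Ms4a7 (ENSRNOG00000020953), a gene of tissue macrophages, was 4.25-fold (3.13 to 5.87) lower, Epsti1 2.31-fold (1.79 to 3.01) lower and the clock output gene Dbp 2.44-fold (1.69 to 3.58) lower. Of the NF-kB list 19 of 19 members were higher (median 0.52 (0.42 to 0.65)). Cluster 11 held Plet1 and Krt79, markers of alveolar macrophages, but fewer than the 3 markers a name required. Its largest differences were MGC105649 (ENSRNOG00000050251), 6.28-fold (5.39 to 7.35) higher, the activin inhibitor Fstl3, 2.74-fold (2.46 to 3.04) higher, and Fcrla (ENSRNOG00000003136), an Fc receptor-like gene, 4.16-fold (3.96 to 4.38) lower (1033 and 248 CPM). Tgm1, Apmap, Clec2l, Hsbp1, Pnpla8, Mdh1, Rbm3 and Abcb10 were 1.56- to 1.91-fold higher in it, and Ccnd1, Sdc3, Glo1, Lgmn, Gngt2, Sod2, Upp1, Popdc2 and Creg1 1.55- to 2.45-fold lower. Of the NF-kB list 12 of 15 measured members were lower in cluster 11 (median -0.15 (-0.19 to -0.09)).

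In NK cell-like cells Ccl4 (ENSRNOG00000011406), a chemokine of activated killer cells, was 4.89-fold (4.51 to 5.30) higher (921 and 4499 CPM), Slfn4 4.19-fold (3.50 to 5.03) higher and the cell cycle inhibitor Cdkn1a (ENSRNOG00000000521) 3.59-fold (2.77 to 4.68) higher, while Gzmbl3, a granzyme gene, and the DNA synthesis genes Lig1 and Dut were 9.76-fold (4.53 to 25.1), 4.27-fold (2.56 to 7.53) and 3.04-fold (2.44 to 3.82) lower. In T cell-like cells Gzmm, Stat3 and Tcf3 were 2.19- to 2.36-fold higher, Ldhb 7.93-fold (5.37 to 12.1) lower and Ifi27 and Crem 2.07-fold and 1.94-fold lower. In B cell-like cells the named differences were small: the ceramidase Acer3 and the chemokine Ccl3 were 2.41-fold (1.93 to 3.02) and 2.07-fold (1.83 to 2.34) higher, Gmpr2, Smchd1, Serpinb6b, Plekha3, Slfn5, Tex9, Lax1 and Tsc22d3 1.55- to 2.16-fold higher, and Tagln2, Crip1, the B cell receptor regulator Cd72, Hist1h2bq, Ran, Mvp, Pdap1 and Snrpd1 1.61- to 2.03-fold lower. Tubb4b and Hmgn2 were 1.83-fold (1.51 to 2.24) and 1.60-fold (1.33 to 1.92) lower in B cell-like cells, with log2 ratios of -1.67 and -1.25 under a stricter filter. Of the NF-kB list 13 of 16 members were higher in NK cell-like, 7 of 9 in T cell-like and 8 of 15 in B cell-like cells.

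Alveolar type 2-like cells, which make surfactant, kept surfactant RNA at like levels in both libraries while a few metabolic genes differed widely. Aqp3 (ENSRNOG00000009797), a water and glycerol channel, was 29.0-fold (23.0 to 37.1) higher in the HIR library (18.3 and 529.5 CPM), the acyl-CoA thioesterase Acot1 (ENSRNOG00000055221) 21.95-fold (14.8 to 34.0) higher and Tesc 3.63-fold (2.95 to 4.49) higher. Scd (ENSRNOG00000013552), the desaturase that makes monounsaturated fatty acids, was 4.95-fold (4.31 to 5.71) lower, and the metallothioneins Mt1 and Mt2A 2.92-fold (2.72 to 3.14) and 2.70-fold (2.28 to 3.21) lower. Of the surfactant list 9 of 17 measured members were higher (median 0.04 (-0.10 to 0.09), where the median over all genes of the class was 0.10), with Sftpc at 212100 and 185300 CPM. The neutrophil chemokine Cxcl3 (ENSRNOG00000028043) was 2.66-fold (2.57 to 2.76) higher and Lcn2 (ENSRNOG00000013973), an iron-sequestering acute phase protein, 1.72-fold (1.66 to 1.77) higher.

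In alveolar type 1-like cells, which form the gas exchange surface, Ramp3 and the Wnt ligand Wnt7a were 3.48-fold (2.25 to 5.56) and 2.85-fold (1.91 to 4.35) lower and Cct6b 3.13-fold lower. Eng, a receptor of endothelium, was 10.5-fold (5.09 to 25.1) higher and Cd24 had 2 and 78 UMIs, but with doublets kept the log2 ratios of Cd24, Eng and Ddit4 were 2.42, -0.19 and 1.69. The HIR cells of this class carried RNA of other cells, with S100a8 at 14.6 and 1902 CPM. After thinning, 26.1% of the HIR cells had an S100a8 UMI. The estimated free RNA share was 12.9% against 0.705% in sham. It was computed from S100a8 and S100a9, so it is not separate evidence. With free RNA subtracted, the NF-kB median of this class was -0.08 instead of 0.95, and the log2 ratios of Il1b and Cxcl2 were -0.57 and -0.56. The subtraction was scaled on S100a8 and S100a9, so these values do not show whether the RNA was free or came with doublets.

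Some genes differed the same way in most classes that expressed them. Bcl3 (ENSRNOG00000043416), an atypical partner of NF-kB proteins, was over 2-fold higher in the HIR library in 8 of 9 classes (median log2 ratio 1.23). Depp1 (ENSRNOG00000023465), a target of FOXO transcription factors, was so in 5 of 5 (3.48), and Gal, the neuropeptide galanin, in 6 of 6 (2.498). Lpl, which frees fatty acids from lipoproteins and is a leading gene of cluster 28, was so in 5 of 6 (1.44). The LIM domain protein gene Csrp2 was so in 4 of 5 (1.51). Gchfr, the feedback regulator of the enzyme that starts tetrahydrobiopterin synthesis, was over 2-fold lower in 5 of 5 classes (-1.49).

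Ligands and receptors of leukocyte traffic differed on both the sending and the receiving side, as RNA levels, which do not show contact or signalling. Of the pairs fixed in advance, 41 had a ligand or receptor over 2-fold apart in any of the 17 compared classes where it reached 50 CPM. With so many classes a pair passes easily. The count also takes in S100a8 and S100a9, whose RNA was present in classes other than neutrophil-like cells. On the neutrophil side, the CXCR2 ligands Cxcl1 and Cxcl2 were higher in classical monocyte-like cells, yet interstitial macrophage-like cells held the most of both (2269 and 4225 CPM and 7597 and 9502 CPM), and Cxcl3 was highest in alveolar type 2-like cells (1146 and 3047 CPM). For adhesion, Selp, Sele and Vcam1 were highest in venous endothelium-like cells of the HIR library, while Vcam1 was 2.95-fold (2.44 to 3.61) lower in adventitial fibroblast-like cells. In the interleukin 1 system, Il1b was highest in neutrophil-like cells of both libraries, as was its decoy receptor Il1r2. In classical monocyte-like cells Il1r2 had 2 and 575 UMIs, too few in sham for a fold. In the interleukin 6 system, Il6 was highest in classical monocyte-like cells of the HIR library (5.35 and 99.4 CPM) and its signalling receptor Il6st in venous endothelium-like cells (73.6 and 180 CPM).

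Nonclassical monocyte-like cells of the HIR library had more of the adhesion ligand Icam1 (3.002-fold (2.67 to 3.38)), the chemokines Ccl3 (2.40-fold (2.29 to 2.52)) and Cxcl16 (2.85-fold (2.52 to 3.24)), the checkpoint ligand Cd274 (2.31-fold (1.87 to 2.87)), the death receptor Fas (3.54-fold (2.74 to 4.61)) and the interleukin 1 antagonist Il1rn (2.83-fold (2.39 to 3.37)), and less of the complement receptor C5ar1 (2.24-fold (1.76 to 2.88)). Cxcr4, the receptor for Cxcl12, was 4.05-fold (3.64 to 4.51) lower in classical monocyte-like cells. The growth factor Vegfa was 3.98-fold (3.18 to 4.99) lower in classical monocyte-like, Gas6, a bridge to dying cells, 2.96-fold (2.53 to 3.47) lower in venous endothelium-like, Il18 6.36-fold (3.16 to 14.5) lower in NK cell-like cells and the macrophage growth factor Il34 2.56-fold (1.97 to 3.37) lower in clusters 3 and 5. Ifngr1, the interferon gamma receptor, was 2.40-fold (1.99 to 2.93) higher in neutrophil-like cells.

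Neutrophil RNA was present in other classes, more so in the HIR library. S100a8 (ENSRNOG00000011557), a calcium-binding alarmin of neutrophils, stood at 22.9 and 254 CPM in general capillary endothelium-like and 22.8 and 293 CPM in B cell-like cells, against 109700 and 173200 CPM in neutrophil-like cells. After thinning each cell to 1000 UMIs, 2.45 and 24.2% of general capillary endothelium-like cells of the sham and HIR libraries had an S100a8 UMI (6.99 and 48.9% unthinned, median UMIs 2738 and 2438), as had 3.3 and 14.1% of T cell-like cells (10.5 and 55.5% unthinned, median UMIs 5545 and 5667). In neutrophil-like cells the thinned shares were 97.9 and 99.6%. With free RNA subtracted, the log2 ratio of S100a8 was 0 in general capillary endothelium-like and B cell-like cells. There the estimate exceeded the S100a8 level in both libraries, so all of it was removed and the 0 decides nothing. The log2 ratio of S100a8 after subtraction was 4.99 in NK cell-like cells (4.32 without subtraction). In T cell-like cells it was -1.16 (1.70 without subtraction). With doublets kept and no subtraction, the T cell-like value was -0.54. Venous endothelium-like cells kept an excess as well. In non-epithelial classes the estimate came from Sftpc and Scgb1a1. It therefore cannot tell whether free RNA accounts for their S100a8. In alveolar type 1-like cells the values were -0.26 for S100a8 and 3.10 for S100a9. There the share was estimated from these same genes, so the subtraction itself fixes what is left of them. The source of the S100a8 RNA in other classes stayed open. Sftpc, the surfactant protein of type 2 cells, stood at 493 and 619 CPM in general capillary endothelium-like cells and the club cell gene Scgb1a1 at 353 and 390.3 CPM. The surfactant and type 2 list went no single way across classes. Its median was 0.62 in general capillary, 0.81 in aerocyte-like and 0.50 in NK cell-like cells. It was 0.02 in classical monocyte-like, 0.07 in B cell-like and -0.43 in adventitial fibroblast-like cells. Sftpc stood at 355 and 360.4 CPM in NK cell-like and 1009 and 342 CPM in adventitial fibroblast-like cells.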

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

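The tests of immediate early genes, of hemoglobin and of genes that the mouse genome lacks were chosen only after the results were seen; the other tests of this part were written down before. Some signals drew attention because they lay outside the comparisons of the report. The sums that follow were taken over all barcodes of a library, before filtering. Genes of hepatocytes summed to 233.3 CPM in sham and 396.4 CPM in HIR, above the limit that a count of 0 allows. Most of it was Tf (141 and 353 CPM), which neutrophil-like cells of these libraries also held, while albumin (Alb) had 1 UMI in sham and 0 in HIR. Genes of liver macrophages and liver endothelium summed to 34.58 and 40.61 CPM, nearly all of it Fcna (33.6 and 39.5 CPM). Genes tied to the sex of the animal summed to 113.2 and 131.8 CPM, so the list gave a signal of like size in both libraries.

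Metallothioneins drew attention because they stood on opposite sides in different classes. In venous endothelium-like cells the log2 ratios of Mt1 and Mt2A were 2.90 and 3.49, higher in the HIR library, and in alveolar type 2-like cells -1.52 and -1.28. With 1 library per group the differences between the classes were not tested.

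Glucocorticoid response genes were higher in the HIR library in all 9 compared non-immune classes. The median of the class medians was 0.972 before and 0.975 after subtraction of each class's free RNA (range over classes 0.685 to 1.405). Free RNA of the size estimated here thus did not account for the difference. The estimate was 2.18% in HIR adventitial fibroblast-like and 3.75% in HIR general capillary endothelium-like cells, so the subtraction could change little. In non-epithelial classes it came from Sftpc and Scgb1a1, and free RNA that these genes do not follow stayed open. Stress of the dissociation is argued against: it raises immediate early genes, whose median of class medians was 0.066 (range -0.224 to 0.284). A different clock time of tissue collection cannot be told apart from HIR, since corticosterone follows the clock. The evening and opposite arms of the clock stood -0.325 apart in the median of 8 classes (range -0.602 to 0.124). This lay between the bounds set for either reading. The opposite arm was Cry1 alone in adventitial fibroblast-like (15.66 and 28.03 CPM in sham and HIR), general capillary endothelium-like and smooth muscle or myofibroblast-like cells. Elsewhere it was Cry1 with Clock or Nfil3, so the contrast rested on few genes. Of the evening genes, Dbp was lower in HIR in every compared non-immune class, while Ciart was higher wherever measured. Surgical stress, fasting, anesthesia and HIR itself may each raise these genes and stayed open and untested, with 1 library per group.

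Neutrophil-like cells of the libraries lay in different clusters. Hemoglobin RNA in sham cells is argued against as the whole cause. Of the 79 sham cells with no larger share of hemoglobin UMIs than the median HIR cell, 50 (63.29%, 51.69 to 73.86) still lay in cluster 4, against 83.1% of all sham cells. A part played by hemoglobin stayed open. A limit of 1% could not decide, since 12 of 378 sham cells lay above it. A lower number of UMIs per sham cell is argued against too: with all cells thinned to 1000 UMIs, 85.37% of the nearest neighbours of sham cells were sham cells, where 19.86% would follow from their share (283 sham and 1142 HIR cells). A candidate explanation that stayed open is that HIR brings neutrophils of another age or state into the lung, but a difference between the libraries in handling or between animals would look alike and was not tested.

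All features carried rat identifiers in samples whose labels name the mouse. Mouse reads counted on a rat annotation are argued against by Fcar and Lgals5, which rats have and the mouse genome lacks. Fcar stood 169.6 times higher (98.84 to 312.5) in neutrophil-like cells than in all other classes, and Lgals5 338.6 times higher in erythroid-like cells, the cells in which rats use them. Ncr3, another such gene, gave 4 UMIs in NK cell-like cells and did not decide. The animals may therefore have been rats, which the labels do not state; whether the organism or the labels are in error stayed open.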

How the results depend on the processing

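The settings without cells under 1000 UMIs, with the clusters of most sham or most HIR cells only, without neutrophils with over 1% hemoglobin UMIs and without the alveolar type 1 cluster that only the HIR library holds were chosen after the data were seen. Every other alternative was fixed in advance. Some gave no value: the nonclassical monocyte-like class was not named in both libraries with no filter, with the stricter filter, at Leiden resolution 2.0 and with each library clustered alone, so its share ratio has no value there and its gene and list results none with the stricter filter. The unnamed clusters have no value with each cell assigned alone. No paired analysis was possible, because there was 1 library per group. Of 337 gene results, 308 kept their direction under every alternative run, as did 72 of 81 list medians and 13 of 18 share ratios. The genes were those named for a large ratio, list examples and pair genes over 2-fold apart. Genes taken only from a pair were run with free RNA subtracted and with doublets kept alone. The lists were the main ones and others with a large median at the edge of the random lists. Such results keep their direction more easily, so the counts do not describe genes and lists in general.

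Share ratios (HIR over sham) moved beyond their interval as follows. With no filter: classical monocyte-like 1.816, erythroid-like 0.531, clusters 3 and 5 1.073, on the other side of 1. With the stricter filter: neutrophil-like 5.579, erythroid-like 0.812, general capillary 0.704, clusters 3 and 5 1.213, again on the other side of 1. With each library clustered alone: erythroid-like 0.673, general capillary 0.851, T cell-like 0.979, clusters 3 and 5 1.158. With each cell assigned alone: neutrophil-like 5.713, classical monocyte-like 1.799, alveolar fibroblast-like 0.724. At Leiden resolution 2.0: general capillary 1.121. Without cells under 1000 UMIs: neutrophil-like 4.371, erythroid-like 0.28. The cause was not tested. Of the other values, 96 stayed within the interval and 8 moved beyond it, those of aerocyte-like, smooth muscle or myofibroblast-like, alveolar type 1-like and venous endothelium-like cells.

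Gene results changed sides in a few cases. With free RNA subtracted, log2 ratios turned to -0.556 for Cxcl2 and -0.566 for Il1b in alveolar type 1-like cells, for S100a8 to -0.391 in aerocyte-like, -0.259 in alveolar type 1-like, -1.158 in T cell-like cells and -1.257 in cluster 11, and for S100a9 to -1.223 in T cell-like cells and -1.052 in cluster 11. Here the subtraction itself removes neutrophil RNA, all of it where the estimate exceeds the level. In alveolar type 1-like cells the estimate came from S100a8 and S100a9 themselves. With doublets kept, Eng in alveolar type 1-like cells turned to -0.185, and S100a8 and S100a9 in T cell-like cells to -0.535 and -0.793; the cause was not tested. Of the other gene values under alternatives, 1387 stayed within their interval and 321 moved beyond it; 29 of the 337 gene results stood on the other side of 0 under some alternative.

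The median of the glucocorticoid list stayed above 0 under every alternative run in the classes named here. With a pseudocount of 1 CPM it was 1.576 in adventitial and 1.59 in alveolar fibroblast-like, 1.252 in aerocyte-like and 1.187 in smooth muscle or myofibroblast-like cells and 1.347 in clusters 3 and 5. With all members with a UMI it was 1.131, 1.059, 0.557 and 0.651 in the same classes without clusters 3 and 5, 0.445 in general capillary and 0.55 in venous endothelium-like cells. It was 1.163 in aerocyte-like cells with doublets kept, 1.104 in general capillary endothelium-like cells with the stricter filter and 1.128 in smooth muscle or myofibroblast-like cells per cell. In the cluster with most sham cells and in that with most HIR cells it was 0.512 and 0.655 in general capillary endothelium-like cells and 0.839 and 0.84 in clusters 3 and 5.

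The NF-kB median was 0.809 in classical monocyte-like, 0.666 in neutrophil-like and 0.598 in venous endothelium-like cells with all members, 0.667 in neutrophil-like cells per cell, 1.166 in venous endothelium-like cells with a pseudocount of 1 CPM and, on the other side of 0, -0.082 in alveolar type 1-like cells with free RNA subtracted. In neutrophil-like cells it was 0.315 in the cluster with most sham cells and 2.216 in that with most HIR cells, and the immaturity list -1.958 and -1.559; in the former, medians of the adhesion (-0.172), matrix (1.148) and ribosomal (0.146) lists changed sides. The unfolded protein response in classical monocyte-like cells was 1.194 with all members. The neutrophil immaturity list was -0.094 per cell, -1.125 with the stricter filter, -0.523 scaled to the median gene and -0.616 with all members. The matrix list of clusters 3 and 5 was -0.663 with free RNA subtracted, -0.569 with the stricter filter, 0.016 in the cluster with most sham cells (on the other side of 0) and -0.181 in that with most HIR cells. With doublets kept, other medians changed sides: the surfactant list in adventitial fibroblast-like (0.264), the matrix list in alveolar type 2-like (-0.119), the erythroid list in B cell-like (-0.192) and the Toll-like receptor list in T cell-like cells (-0.124). The cause was not tested. The median over all genes was -0.26 in neutrophil-like and 0.10 in alveolar type 2-like cells, so scaling raised values of the former and lowered those of the latter by as much. Neutrophil-like list medians between -0.26 and 0 stand above 0 once scaled: glucocorticoid, NET, immediate early, unfolded protein, mitochondrial, apoptosis, surfactant and hypoxia. These 8 are not among the 81 list medians counted above. Of the pairs, 41 passed with free RNA subtracted and 43 with doublets kept. Genes under 20 CPM in small classes were too shallow for a comparison.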

Other observations

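No test is reported in this part. Interferon-induced genes were higher in the HIR library in some classes and not in others. Of the type I interferon list, 9 of 9 measured members were higher in neutrophil-like cells (median log2 ratio 0.59 (0.34 to 0.84)). Within cluster 22, which held 64 sham and 1253 HIR cells, the median was 1.95. The list member Ifit3 was among the 10 leading genes of cluster 4, which held 83.1% of the sham neutrophil-like cells. Members higher were 12 of 13 in aerocyte-like (0.48 (0.29 to 0.64)) and 9 of 11 in general capillary endothelium-like cells (0.40 (0.31 to 0.54)). They were 3 of 8 in B cell-like (-0.09), 3 of 6 in interstitial macrophage-like (-0.04) and 3 of 6 in alveolar type 1-like cells (0.09). In classical monocyte-like cells they were 3 of 6 (0.17) and in venous endothelium-like cells 4 of 13 (-0.17). Isg15, a ubiquitin-like modifier, stood at 106 and 242 CPM in aerocyte-like cells. Of the interferon gamma list the medians were 0.55 in neutrophil-like, 0.40 in NK cell-like and 0.33 in T cell-like cells but 0.01 in general capillary endothelium-like, -0.03 in B cell-like, -0.19 in interstitial macrophage-like and -0.20 in venous endothelium-like cells, with the guanylate-binding protein gene Gbp5 at 48.8 and 136 CPM in NK cell-like cells. The Toll-like receptor signalling list, which also holds S100a8, S100a9, Ager and Hmgb1, had medians above 0 in all 17 compared classes. They ran from 0.23 in cluster 11 and 0.27 in neutrophil-like cells to 0.91 in NK cell-like cells. The highest were 1.12 in nonclassical monocyte-like (0.16 with members under 20 CPM) and 1.18 in aerocyte-like cells. In aerocyte-like cells it was 0.29 with members under 20 CPM, 0.44 with the stricter filter and 0.48 with doublets kept. In T cell-like cells it was 0.43, or -0.12 with doublets kept. S100a8 and S100a9 in other classes include neutrophil RNA, so these medians do not measure the receptors alone. Inflammasome genes had a median of 0.30 in nonclassical monocyte-like cells.

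Ribosomal protein genes were lower in 69 of 72 cases in neutrophil-like cells of the HIR library (median -0.68 (-0.74 to -0.62), or -2.86 with free RNA subtracted and 0.15 within cluster 4, against a median of -0.26 over all genes of the class) and had a median of -0.26 in classical monocyte-like cells. The free RNA share behind -2.86 was 2.05% in sham and 9.80% in HIR neutrophil-like cells. It followed Scgb1a1 (368 and 2264 CPM), which 47.6% of the sham and 36.6% of the HIR cells held, while Sftpc stood at 445 and 370 CPM. The share may therefore be too high for most HIR cells. Genes of hypoxia and glycolysis had medians of -0.39 (-0.58 to -0.19) in NK cell-like (10 of 13 members lower), -0.29 (-0.39 to -0.13) in adventitial fibroblast-like, -0.20 in smooth muscle or myofibroblast-like and 0.18 in alveolar type 2-like cells. Of oxidative stress and iron, the lists had medians of 0.20 in clusters 3 and 5 and 0.12 and 0.12 in nonclassical monocyte-like cells, where the heme-degrading enzyme Hmox1 stood at 359.8 and 1221 CPM. In interstitial macrophage-like cells the list of alternative activation had a median of 0.37, with the hemoglobin scavenger receptor Cd163 at 167 and 389.7 CPM and the mannose receptor Mrc1 at 1086 and 1851 CPM, and phagocytosis genes -0.03. MHC class II genes stood at -0.16 there and 0.09 in B cell-like cells, naive lymphocyte genes at 0.21 in T cell-like and effector genes at 0.08 in NK cell-like cells. Of the apoptosis list the median was 0.13 in nonclassical monocyte-like cells, and of acute phase proteins 0.13 in alveolar type 2-like cells. NET and oxidase genes stood at -0.09 in neutrophil-like cells, on the other side of 0 when scaled to the median gene, and at 0.47 in nonclassical monocyte-like cells, and mitochondrially encoded genes at 0.15 in T cell-like cells. Immediate early genes stood at -0.31 in T cell-like cells. Azurophil granule genes had too few measured members for a median; Elane, neutrophil elastase, stood at 16.3 and 69.6 CPM in neutrophil-like cells.

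Genes of other tissues were summed over all barcodes of the sham and HIR libraries, before filtering. Erythroid genes gave 27320 and 11770 CPM. Genes of thymus or lymph node gave 517.4 and 444.0 CPM (of which Ccl21 482 and 415 CPM). Megakaryocyte or platelet genes gave 96.97 and 65.04 CPM and cardiac or skeletal muscle genes 24.78 and 20.59 CPM.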
